A study of Homo sapiens with 6 samples.

How the data were processed

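RNA sequencing data from libraries labelled HepG2 were analysed, 3 with a control shRNA and 3 with an shRNA against STAT3. Per the labels, the cells were kept in DMEM with fetal bovine serum and antibiotics, the lines were made with shRNA, and total RNA was used. The library kit, its strand setting, the aligner, the counting program, the genome build and the annotation are not given in the sources used here. Without a known strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart, and reads shared by near-identical copies can be split between them in ways that are not known.

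The deposited table gave whole-number counts per gene for each of the 6 libraries, with no normalization visible in the values: the totals differ between libraries. It held 27452 rows, 26420 with a versioned Ensembl gene identifier and 1032 named by the submitters only with a running number, of which 508 were tested and 69 called (52 higher, 17 lower). In 23 rows the gene symbol had turned into a date, and all 23 were replaced by identifier from a table of gene names. Groups were taken from the treatment label, and the library numbers from the titles. Genes were matched by identifier without its version to GENCODE 29, which found 25996 of the 26420 identifiers and 14373 of the 14491 tested ones. The annotation was used only for gene type, transcript length, GC content and the order of genes on chromosomes. Length and GC content were those of the longest annotated transcript of a gene. As the build of the deposited table is not named, no coordinates are given. Levels of the gene XIST and of genes on chromosome Y were not reported.

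Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15), which left 14999, and libraries were scaled by TMM factors, which assume that most genes do not differ. Changes that affect most genes in one direction are therefore not visible in these values. CPM values are counts divided by the scaled library size, on the usual CPM scale. Each gene was tested with the quasi-likelihood F test with robust dispersion, two-sided, with a model of group only, and p-values were adjusted by the Benjamini-Hochberg method over all 14999 genes at an FDR of 0.05. The SE of a log2 fold change was computed as its size divided by the square root of the F statistic. Total counts were 17408543 to 25862027 per library, and a count of 0 was taken to allow up to 3 counts.

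The 39 gene lists, the tests and the rule for named genes were fixed before the data were examined, with STAT3 left out of every list. Lists with 5 or more tested members, 35 in all, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 35 lists. Genes were named by rule: STAT3; the 12 protein-coding genes with the largest log2 fold change in each direction with FDR under 0.05, a mean of at least 5 CPM and no overlap between groups; and for each list up to 4 called members with the smallest FDR, or, if none was called, up to 2 with the highest mean CPM. This gave 149 genes, 142 of them called. Not every gene picked by the rule is printed. Others are named only where the text says that they were chosen after their values were seen. Library measures were compared with exact two-sided permutation tests over the 20 assignments of the 6 libraries, whose smallest p is 0.1.

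Libraries of a group were compared with each other by a chi-square test over genes, which gave 4.20 to 43.0 per degree of freedom over the pairs within groups, far above the 1 that sampling noise alone gives, so no pair is a repeat of one library. Windows of a gene with its 40 neighbours, all with a mean of at least 1 CPM, were compared with 100 shuffles of gene order. Joined windows beyond the largest shuffle made 3 segments, and this search was chosen after the data were seen. Each of 135 ribosomal protein and respiratory chain genes was matched to the 10 tested genes outside both lists nearest in log2 length and GC content, each divided by its SD, and the median of the matched genes was bootstrapped over members. A window needs all 40 neighbours, so the ends of a segment are approximate. Genes next to a segment or at the end of a chromosome may be missed.

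The procedure was tested on simulated counts for this comparison of STAT3 shRNA with control shRNA, over 14999 genes with means, dispersions and library sizes of the real data. It called 28.4% of 67 genes changed 1.5-fold, 65.7% of 67 changed 2-fold and 89.4% of 66 changed 4-fold, and 5.43% of calls were false. Far fewer genes were changed than the real data called, which makes the FDR threshold stricter. These shares therefore need not hold for the real data. A list of 40 genes shifted by -0.5 on the log2 scale was called, and 0 of 35 other lists were. Simulated genes were drawn independently of each other. The simulation therefore does not test how often camera calls a list of correlated genes falsely. Alternatives were median-of-ratios, upper-quartile and total-count scaling, no filter or a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a model with the library number as a block, leaving out each library in turn, an FDR of 0.01, a test against a 1.5-fold change, an estimated correlation for camera, the fry test, and leaving out the segment genes. The segment genes were removed from the gene counts without a new fit or adjustment, while camera was run again without them. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.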

Results

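Gene expression was measured by RNA sequencing in libraries labelled HepG2, an established human liver cancer line, in which lines had been made with a control short hairpin RNA (shRNA) or with an shRNA against STAT3. An shRNA is processed in the cell into a short interfering RNA that lowers the messenger RNA it matches. STAT3 is a transcription factor that cytokines such as interleukin 6 activate through Janus kinases. Each group had 3 libraries, 6 in all. The 3 control libraries held 17408543, 19283150 and 20133064 counts over all genes, and the 3 STAT3 shRNA libraries held 25862027, 19719848 and 17694642. At these depths a gene with no count in a library could still lie at up to 0.175 CPM in the shallowest library and 0.113 CPM in the deepest (CPM, counts scaled to a common library size, taking 3 counts as the floor), which covers counting error only. The labels number the libraries 1 to 3 in each group. They do not say whether the numbers stand for separate cultures or for different shRNA sequences, so p-values measure only the spread between these libraries, which may be technical. Any difference between the constructed lines that is not due to the shRNA falls together with the comparison.

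The first principal component of log2 CPM held 56.4% of the variance and separated the groups. The second held 20.9% and spread the libraries within groups. On it, control libraries 1, 2 and 3 lay at 44.3, -1.56 and -27.5, and STAT3 shRNA libraries 1, 2 and 3 at 6.32, -31.1 and 9.48. The number of genes with at least 1 count was 20556 ± 470 (SD, n = 3) in the control libraries and 21592 ± 422 (n = 3) in the STAT3 shRNA libraries, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give. Genes of the mitochondrial genome took 3.21 ± 0.598% and 3.39 ± 0.700% of counts (exact permutation p = 0.9, n = 3 per group). Ribosomal protein genes took 7.17 ± 1.05% and 6.01 ± 0.340% (exact permutation p = 0.2, n = 3 per group). Some shares separated the groups fully, each with an exact permutation p of 0.1 (n = 3 per group). Rows that the table names without a gene identifier took 0.735 ± 0.0231% and 0.833 ± 0.00424% of counts, histone genes 0.0122 ± 0.000690% and 0.0135 ± 0.000504%, and the imprinted RNA H19, chosen after its values were seen, 0.826 ± 0.273% and 0.317 ± 0.0502%.

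The first question was whether STAT3 itself was lower. STAT3 (ENSG00000168610.14) lay at 261.5, 246.7 and 246.3 CPM in the control libraries and at 34.8, 35.8 and 36.2 CPM in the STAT3 shRNA libraries. Its mean fell from 252 ± 8.67 to 35.6 ± 0.730 CPM (SD, n = 3 per group), a 7.06-fold lower level with a log2 fold change of -2.82 ± 0.0845 (SE; edgeR quasi-likelihood test, adjusted p = 2.19e-07). Every library therefore carried the STAT3 level that its label names.

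The comparison of the groups asked which genes differed with the STAT3 shRNA. In the text that follows, log2 fold changes are STAT3 shRNA over control shRNA and are given ± SE, and levels are mean CPM ± SD with n = 3 per group. Of 14999 genes tested, 2627 passed a false discovery rate (FDR) of 0.05, or 17.5%, of which 1408 were higher and 1219 lower in the STAT3 shRNA libraries. A change of at least 2-fold was met by 924 of them, 595 higher and 329 lower. Among the called genes, 2621 had no overlap between the 3 control and the 3 STAT3 shRNA libraries. Over all tested genes 35.7% had none, against the 10% that chance gives. STAT3 was not the gene with the largest change: 179 called genes had a larger fitted fold change, 109 higher and 70 lower. With library totals in place of composition-corrected scaling, 68.7% of 2790 called genes were higher, and with upper-quartile scaling 62.3% of 2667, against 53.6% here. The DESeq2 Wald test turned the balance, with 1373 higher and 1445 lower, or 48.7% higher. Leaving out control library 1 gave 4098 genes, control library 2 gave 1527, STAT3 shRNA library 1 gave 1462 and STAT3 shRNA library 3 gave 1475.

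Among protein-coding genes with a mean of at least 5 CPM, the strongest loss was of SLC12A3, the thiazide-sensitive sodium-chloride cotransporter, which fell from 369 ± 3.8 to 1.86 ± 0.43 CPM, a log2 fold change of -7.61 ± 0.153 (edgeR adjusted p = 3.20e-08). ALPI, an alkaline phosphatase of the intestine, fell from 1182 ± 207 to 8.33 ± 2.05 CPM (-7.15 ± 0.219). Its value is uncertain where reads are shared with the related placental and germ cell genes, which lie next to it. The protease inhibitor family member WFDC1 fell from 39.5 ± 5.3 to 0.971 ± 0.0652 CPM, and the aldo-keto reductase AKR1C1 from 27.2 ± 2.48 to 1.43 ± 0.474 CPM. AKR1C1 is nearly identical to AKR1C2, which rose (0.94 ± 0.0914), so the split of reads between them is uncertain. The extracellular matrix genes COL15A1 (-3.59 ± 0.221) and FN1, or fibronectin (-3.24 ± 0.309), fell, as did the focal adhesion gene TNS4 (-3.57 ± 0.174), the carboxypeptidase CPM (-3.48 ± 0.124), the transcription factor KLF12 (-3.44 ± 0.296) and the glycosyltransferase family member GALNTL6 (-3.54 ± 0.247). AGTRAP, which encodes a protein that binds the angiotensin II receptor, fell (-3.08 ± 0.175) and the kinase activator family member MOB3B (-2.90 ± 0.171).

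The largest rise among the same genes was of FOLH1, a folate hydrolase also known as prostate-specific membrane antigen, from 0.184 ± 0.0428 CPM, or 3 to 4 counts per control library, to 16.7 ± 0.691 CPM (6.47 ± 0.208; edgeR adjusted p = 2.50e-07). DPYSL3, a cytoskeletal regulator of growing neurites, rose from 2.54 ± 0.484 to 158 ± 7.87 CPM, and the epithelial keratin KRT4 from 1.23 ± 0.382 to 51.6 ± 1.79 CPM. PAGE1, a member of the cancer-testis antigen family with many close copies, rose from 3.15 ± 0.484 to 112 ± 7.19 CPM. LAMA1, a laminin chain of basement membranes, rose from 28.7 ± 1.97 to 318 ± 19 CPM (3.47 ± 0.0993). Endoglin (ENG), a co-receptor for TGF-beta, rose from 1.23 ± 0.275 to 26.9 ± 0.614 CPM, and HSD17B13, an enzyme of liver lipid droplets, from 0.615 ± 0.377 to 10 ± 1.17 CPM. The unconventional myosin gene MYO15B (4.48 ± 0.184), the neuronal pentraxin receptor NPTXR (3.30 ± 0.251), the ephrin receptor EPHB2 (3.29 ± 0.174), the angiogenesis inhibitor VASH1 (3.21 ± 0.315) and the splicing factor SRRM3 (3.19 ± 0.224) also rose.

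**Figure D1:**
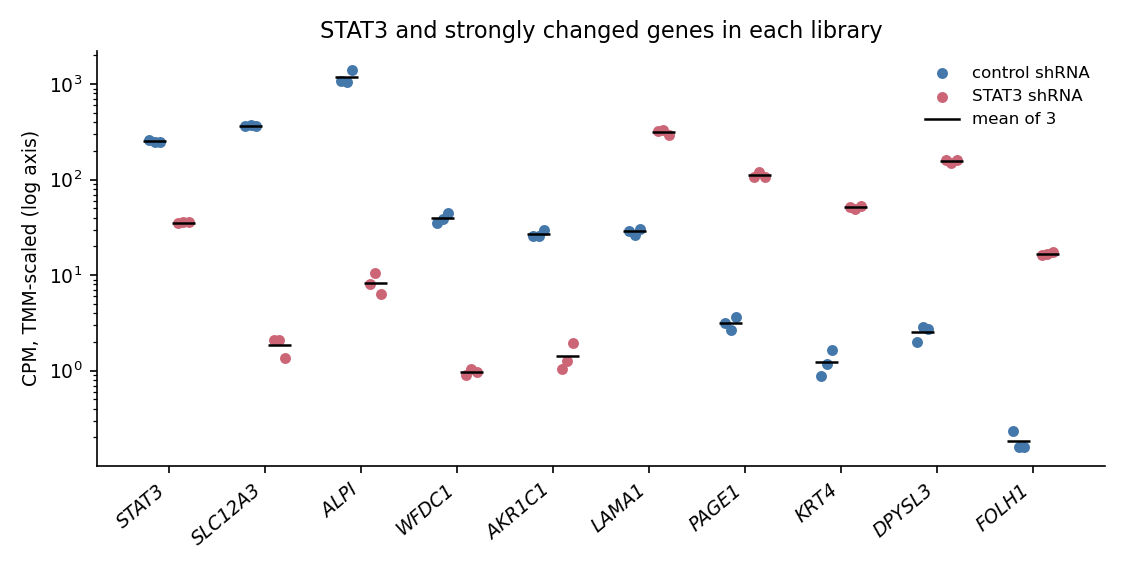
Each point is the CPM of one library on a log axis, for STAT3, the 4 genes with the largest falls and 5 of the genes with the largest rises under the naming rule, with control shRNA libraries in blue, STAT3 shRNA libraries in red and the mean of 3 libraries as a bar. STAT3 lies at 252 CPM on average in the control libraries and 35.6 CPM in the STAT3 shRNA libraries, with no overlap.

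**Figure D2:**
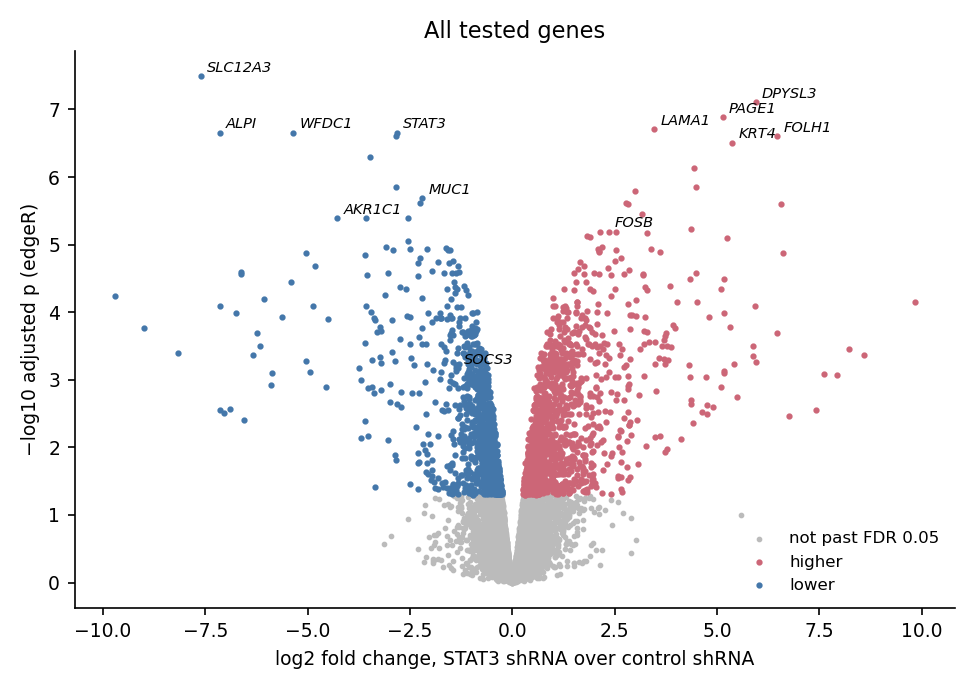
Each point is one of the 14999 tested genes, with its log2 fold change on the x axis and the negative log10 of the edgeR adjusted p on the y axis; red and blue mark the 1408 higher and 1219 lower genes. Genes with no counts in one group are drawn at their fitted value, which is not a measured size.

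Gene groups fixed before the data were examined were then compared, 39 lists in all, of which 35 had at least 5 tested members. The camera set test, which compares a list with all other tested genes, called 6 of the 35 lists at an adjusted p of 0.05 with a preset correlation of 0.01. With a correlation estimated per list it called 0, the smallest adjusted p being 0.393 and 1 list having an unadjusted p under 0.05. The fry rotation test, which asks only whether a list's genes move one way, called 22. Another split of the 6 libraries, which mixes the groups, gave 7 called lists by camera, so the list calls rest on less than the gene calls. In each paragraph the counts of members are those past FDR 0.05 over all genes tested, followed by the count adjusted over the list alone.

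Among 33 tested genes described as direct STAT3 targets outside the acute phase, 3 rose and 10 fell, or 4 and 11 adjusted over the list alone, and camera did not call the list (median log2 fold change -0.10, camera adjusted p = 0.101). MUC1, a membrane mucin, fell from 175 ± 11 to 37.9 ± 2.52 CPM (-2.21 ± 0.0958). The nicotinamide methyltransferase NNMT fell (-1.18 ± 0.0873), the survival kinase PIM2 (-1.52 ± 0.158) and SOCS3, the feedback inhibitor of cytokine receptors, (-1.33 ± 0.167). The 3 targets that rose were the anticoagulant PROS1 (1.24 ± 0.115), the AP-1 gene FOS (0.86 ± 0.0917) and the membrane protease MMP14 (0.79 ± 0.155), the last chosen after its values were seen. Of 37 JAK-STAT receptors, kinases and inhibitors, 4 rose and 5 fell, the same counts adjusted over the list alone (median -0.05, camera adjusted p = 0.580). That median turned to 0.01 with upper-quartile scaling and 0.05 with library totals, which gave 3 lower. SOCS7 (0.59 ± 0.103) and the interferon receptor chain IFNAR2 (0.56 ± 0.101) rose, and the oncostatin M receptor OSMR fell (-0.62 ± 0.132), a call lost in 1 of 14 alternative fits. Leaving out control library 2 or STAT3 shRNA library 1 or 3 brought these counts to 2 higher and 2 lower, and leaving out STAT3 shRNA library 2 brought the lower count to 2.

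Interferon-stimulated genes went both ways: of 40 tested, 5 rose and 7 fell, or 9 and 7 adjusted over the list alone (median 0.04, camera adjusted p = 0.961, with camera pointing up and fry down). The higher count was 8 with upper-quartile scaling and 9 with library totals. IFITM3, which blocks virus entry and has close paralogs, fell from 426 ± 56.7 to 203 ± 4.69 CPM, and the oligoadenylate synthetase genes OASL (-1.10 ± 0.117) and OAS1 (-0.75 ± 0.0977) fell. SAMD9L, an antiviral factor, rose (2.21 ± 0.244). Of 6 tested acute-phase genes, 2 rose and 1 fell, or 3 and 1 adjusted over the list alone (median 0.03, camera adjusted p = 0.447). Lipocalin LCN2 rose from 2.65 ± 0.147 to 15.3 ± 1.61 CPM and SAA1 from 1.03 ± 0.24 to 2.69 ± 0.264 CPM, while C4BPA, a complement regulator, fell from 4.66 ± 0.337 to 0.611 ± 0.294 CPM. Among 19 NF-kB targets 5 rose and 2 fell, or 7 and 3 adjusted over the list alone (median 0.32, camera adjusted p = 0.310). The cytokine IL32 rose from 9.66 ± 2.22 to 61.4 ± 4.64 CPM and the feedback inhibitor TNFAIP3 (0.61 ± 0.0904), while complement C3 (-0.87 ± 0.0753) and the coactivator BCL3 (-0.76 ± 0.139) fell. The count of 5 higher NF-kB targets became 2 without control library 2 or without STAT3 shRNA library 1 or 3, and 3 without STAT3 shRNA library 2.

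Immediate early and AP-1 genes were called higher as a list: 10 of 27 rose and 2 fell, or 12 and 3 adjusted over the list alone (median 0.22, camera adjusted p = 0.0355; adjusted p = 0.534 with an estimated correlation). FOSB rose from 16.4 ± 2.42 to 84.2 ± 3.2 CPM (2.36 ± 0.123), as did FOS, given above, and the antiproliferative gene BTG2 (0.83 ± 0.103). The nuclear receptor NR4A2 fell (-1.61 ± 0.18), and it lies in a chromosome segment described later. The camera call was lost without control library 1 (adjusted p = 0.0976), control library 2 (0.0659) or STAT3 shRNA library 2 (0.0556). Over the 9 camera alternatives other than the estimated correlation the adjusted p ranged from 0.00792 to 0.0976, and 5 of the 9 called the list, while fry gave 0.00998. The median was 0.33 without control library 3. Without control library 1, 5 members were lower.

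Cholesterol synthesis and uptake genes fell together: 17 of 25 were lower and 1 higher, or 19 and 1 adjusted over the list alone, with a median of -0.50 (camera adjusted p = 2.79e-07). The camera adjusted p was 0.393 with an estimated correlation and ranged from 6.81e-08 to 2.38e-06 over its 9 other alternatives, and fry, which tests against no change, gave 0.00132. FDFT1, or squalene synthase, fell from 388 ± 23.8 to 239 ± 4.64 CPM (-0.70 ± 0.0818). DHCR7, the last enzyme of cholesterol synthesis, fell (-0.70 ± 0.0842), the sterol dehydrogenase NSDHL (-0.79 ± 0.102) and farnesyl diphosphate synthase (FDPS) (-0.73 ± 0.104). The 1 higher member was not called without control library 2 or 3 or without any one STAT3 shRNA library. Of 26 fatty acid and triglyceride synthesis genes, 9 fell and 3 rose, or 10 and 4 adjusted over the list alone (median -0.16, camera adjusted p = 0.101). Stearoyl-CoA desaturase (SCD) fell from 1034 ± 76.6 to 607 ± 14 CPM and the acyl-CoA synthetase ACSL1 (-1.16 ± 0.134), while DGAT2, which makes triglyceride, rose (1.36 ± 0.181) and the elongase ELOVL2 from 0.222 ± 0.153 to 3.0 ± 0.432 CPM. The lower count was 5 with library totals, without control library 2 or without STAT3 shRNA library 1 or 3.

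Fatty acid oxidation, peroxisome and ketone genes showed few calls, with 2 of 30 higher and 1 lower, the same counts adjusted over the list alone (median -0.10, camera adjusted p = 0.580). PPARGC1A, a coactivator of mitochondrial genes, rose (0.87 ± 0.159), as did the oxidation enzyme HADHB (0.38 ± 0.0829), and the carnitine enzyme CPT2 fell (-0.37 ± 0.0915). The HADHB call was lost in 3 and the CPT2 call in 6 of 14 alternative fits. Without control library 1 the counts were 4 higher and 6 lower, without control library 2 or STAT3 shRNA library 1 or 3 they were 1 and 0, and without STAT3 shRNA library 2 the lower count was 0. Library totals gave 4 higher and 0 lower.

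Glycolysis and hypoxia-inducible genes were lower as a list: 13 of 39 fell and 2 rose, or 21 and 2 adjusted over the list alone, with a median of -0.33 (camera adjusted p = 4.14e-06). The camera adjusted p was 0.534 with an estimated correlation and ranged from 3.48e-07 to 6.77e-05 over its 9 other alternatives, and fry gave 0.0132. The neuronal-type glucose transporter SLC2A3, which has a close paralog, lay at 6.45 ± 1.6 CPM in the control libraries and 0.0828 ± 0.0763 CPM in the STAT3 shRNA libraries, where it was at or near 0 counts. Hexokinase HK2 fell from 82 ± 6.35 to 44 ± 5.5 CPM, the collagen cross-linking enzyme LOX from 40.3 ± 4.05 to 14 ± 2.82 CPM and the kinase PDK1, in one of the chromosome segments, (-1.05 ± 0.156). The higher count was 1 without STAT3 shRNA library 3. Of 14 gluconeogenesis and glycogen genes, 2 rose and 4 fell, or 2 and 6 adjusted over the list alone (median -0.19, mean 0.02, camera pointing down with adjusted p = 0.310). IGFBP1, an insulin-repressed secreted protein, rose from 0.458 ± 0.077 to 4.38 ± 0.83 CPM and the glycogen phosphorylase PYGB (0.54 ± 0.0884), while IRS1 (-0.82 ± 0.137) and the glycogen-targeting subunit PPP1R3C (-0.62 ± 0.126) fell, the last a call lost in 1 of 14 alternative fits. The 4 lower genes became 2 without control library 2 or STAT3 shRNA library 1 and 1 without STAT3 shRNA library 3.

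**Figure D3:**
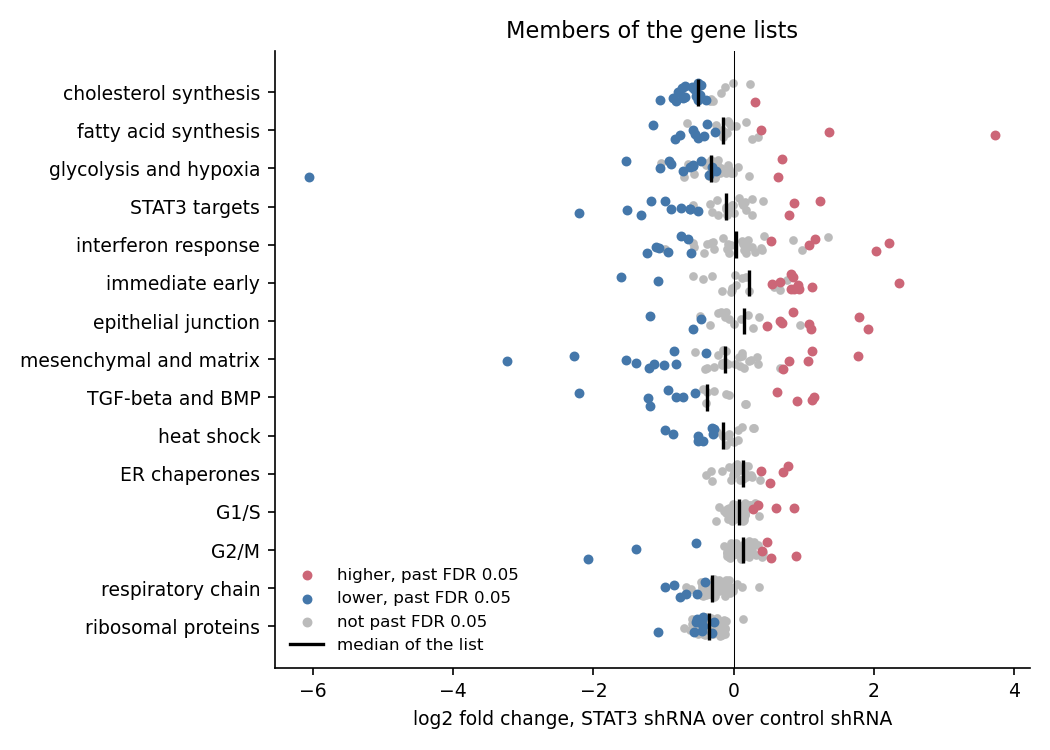
Each point is a member of one of 15 gene lists, at its log2 fold change of STAT3 shRNA over control shRNA on the x axis, red or blue where the gene passed FDR 0.05 as higher or lower, and the bar is the median of the list. The cholesterol synthesis list has its median at -0.50 with 17 of 25 members lower.

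Many transcripts of the hepatocyte were near the floor in both groups. Albumin (ALB) had 2, 0 and 0 counts in the control libraries and 0, 0 and 3 in the STAT3 shRNA libraries. ALB, APOA1, APOA2, APOC1, AHSG, HP, FGG and SERPINC1, 8 genes chosen after their values were seen, summed to at most 0.264 CPM in a control library and at most 0.654 CPM in a STAT3 shRNA library. The list named 38 hepatocyte markers. Of the 26 with a row in the table, 11 reached 1 CPM in any library and 11 had no more than 3 counts in each. Among the 11 tested, 4 rose and 1 fell, the same counts adjusted over the list alone (median 0.41, also with a gene at 0 counts set at its bound, camera adjusted p = 0.310). HPD, an enzyme of tyrosine breakdown, fell from 184 ± 25.9 to 58.1 ± 2.76 CPM. HNF4A, a transcription factor of hepatocyte identity, rose from 1.51 ± 0.26 to 6.58 ± 1.41 CPM and the transferrin receptor TFR2 (0.63 ± 0.11), and NR5A2, a nuclear receptor, was at 0 counts in all 3 control libraries and at 2.41 ± 0.666 CPM with the STAT3 shRNA, at least 14.6-fold higher against 3 counts per library. The lower count was 2 without control library 1.

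Of 11 tested fetal liver and progenitor genes, 5 rose and 3 fell, the same counts adjusted over the list alone (median 0.23, camera adjusted p = 0.406). The transcription factor TBX3 fell (-1.12 ± 0.0854), and the cell surface marker EPCAM (1.78 ± 0.161), the imprinted placental gene PEG10 (0.95 ± 0.118) and SOX4 (0.69 ± 0.105) rose. Complement and coagulation genes had 2 higher and 5 lower of 13, or 3 and 6 adjusted over the list alone (median -0.38, camera adjusted p = 0.301), including a rise of PROS1, given above, and of SERPINF2 (1.90 ± 0.283) and a fall of C4BPB (-0.53 ± 0.0799). That lower count was 3 without control library 2 or STAT3 shRNA library 3. Of 14 cytochrome, conjugation and bile acid transport genes, 5 rose and 2 fell, or 5 and 4 adjusted over the list alone (median 0.30, also with a gene at 0 counts set at its bound, camera adjusted p = 0.340). The exporter ABCG2 fell from 61.8 ± 5.15 to 23.2 ± 1.11 CPM, and the uptake transporter SLCO1B3 (1.49 ± 0.196) and CYP1A1 (0.96 ± 0.132) rose. CYP3A7, a fetal cytochrome with close paralogs, was at 0 counts in all 3 control libraries and at 1.52 ± 0.414 CPM with the STAT3 shRNA, at least 9.24-fold higher against 3 counts per library. The count of 5 higher genes was 3 without control library 2 or STAT3 shRNA library 1 or 3, and the lower count was 1 without STAT3 shRNA library 1 or 3.

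Markers of other cell types were measured as well. Of 8 tested cholangiocyte markers, 4 rose and 2 fell, the same counts adjusted over the list alone (median 0.44, camera adjusted p = 0.427). MMP7 rose from 5.82 ± 1.29 to 19.8 ± 2.35 CPM, the annexin ANXA4 rose (0.75 ± 0.0884), and MUC1 fell as given above. The lower count was 1 without STAT3 shRNA library 1 or 3. Of 8 stellate cell and fibroblast markers, 1 rose and 2 fell, or 2 and 3 adjusted over the list alone (median 0.25, also with a gene at 0 counts set at its bound, mean -0.86, or -0.29 with that bound, camera pointing down with adjusted p = 0.730). COL1A1, a chain of type I collagen, fell from 40.3 ± 2.86 to 15.3 ± 1.1 CPM, actin ACTA2 rose (1.06 ± 0.214), a call lost in 1 of 14 alternative fits, and FAP went from 0.819 ± 0.287 CPM to 0 counts in all 3 STAT3 shRNA libraries, at least 5.80-fold lower. The higher count was 2 with upper-quartile scaling, with library totals or without control library 1 or 3, and 0 without STAT3 shRNA library 1. Among 7 leukocyte markers with a row, CD68, the 1 tested gene, rose (0.83 ± 0.173), a call lost without STAT3 shRNA library 3, 1 of 14 alternative fits, and is 1 of 1 adjusted over the list alone. The 1 tested endothelial marker, CDH5, lay at 1.31 ± 0.394 and 0.75 ± 0.146 CPM and was not called, with edgeR giving 0 calls over all genes and adjusted over the list alone, 0 at an unadjusted p under 0.05, and DESeq2 and limma-voom 0. Of 3 tested markers of other laboratory lines, keratin KRT17 fell from 685 ± 91 to 385 ± 26.3 CPM, 1 lower and 0 higher, or 2 lower and 1 higher adjusted over the list alone (median -0.83), with DESeq2 and limma-voom also giving 0 higher and an unadjusted p giving 1 higher.

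Iron and ferroptosis genes changed in both directions, 5 of 29 higher and 9 lower, the same counts adjusted over the list alone (median -0.06, or 0.04 with library totals, camera adjusted p = 0.324). The ferritin heavy chain FTH1, which has many processed copies, rose from 3364 ± 239 to 6947 ± 279 CPM. BMP6, a ligand that controls hepcidin, fell (-1.22 ± 0.12) and the inhibitor SMAD6 (-0.93 ± 0.124). The higher count was 3 without STAT3 shRNA library 3. Of 27 NRF2 targets, 5 rose and 9 fell, or 5 and 12 adjusted over the list alone (median -0.16, camera adjusted p = 0.138). They included AKR1C1, which fell, and AKR1C2 and FTH1, which rose, as given above. The lower count was 5 without control library 2 or STAT3 shRNA library 3 and 4 without STAT3 shRNA library 1.

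Of 33 ATF4 and amino acid response genes, 6 rose and 6 fell, the same counts adjusted over the list alone (median -0.13, mean 0.00188, camera pointing down with adjusted p = 0.554). GDF15, a stress-induced cytokine, rose from 14.4 ± 2.43 to 45.8 ± 5.8 CPM and the folate enzyme ALDH1L2 (1.15 ± 0.208), while the amino acid transporter SLC7A5 (-0.52 ± 0.0831) and TRIB3 (-0.70 ± 0.127) fell. The lower count was 2 without control library 2 or STAT3 shRNA library 3 and 3 without STAT3 shRNA library 1. Of 28 endoplasmic reticulum chaperone and unfolded protein response genes, 4 rose and 0 fell, the same counts adjusted over the list alone (median 0.14, camera adjusted p = 0.101). By DESeq2, by limma-voom and at an unadjusted p under 0.05, 0 were lower as well. HERPUD1, of protein degradation at that organelle, rose from 68 ± 0.395 to 110.4 ± 3.73 CPM, PPP1R15A (0.78 ± 0.124), the disulfide isomerase PDIA6 (0.39 ± 0.0754) and the stress sensor ERN1 (0.52 ± 0.115). The ERN1 call was lost in 3 and the PDIA6 call in 1 of 14 alternative fits, and the count of 4 higher genes was 8 without control library 1 and 2 without control library 2, and 2 were lower without control library 1. Library totals gave 7 higher.

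Heat shock genes were called lower as a list, with 8 of 21 lower and 0 higher, the same counts adjusted over the list alone (median -0.15, camera adjusted p = 0.0417; adjusted p = 0.534 with an estimated correlation). By DESeq2 and limma-voom 0 were higher, and at an unadjusted p under 0.05, 1 was. HSPD1 fell from 1552 ± 145 to 852 ± 50.8 CPM and HSPE1 (-0.98 ± 0.238); both encode subunits of the mitochondrial chaperonin, unlike the cytosolic proteins the list is named for, and both lie in one of the chromosome segments. The co-chaperones AHSA1 (-0.51 ± 0.113) and STIP1 (-0.31 ± 0.0816) fell. The HSPE1 call was lost in 5, the AHSA1 call in 3 and the STIP1 call in 6 of 14 alternative fits. The list call rested on few data: it was lost without the segment genes (adjusted p = 0.0918), without control library 1 (0.0976) or 2 (0.0788) and without STAT3 shRNA library 2 (0.0737) or 3 (0.0775). Over the 9 camera alternatives other than the estimated correlation the adjusted p ranged from 0.00792 to 0.0976, and 3 of the 9 called the list, while fry gave 0.0188. The median was -0.07 without control library 1. The 8 lower genes became 1 without control library 2 or STAT3 shRNA library 1 or 3, 4 without control library 3 and 5 without STAT3 shRNA library 2, and 1 was higher without control library 1. With upper-quartile scaling 4 were lower, and with library totals 3.

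Of 48 G1/S and replication genes, 4 rose and 0 fell, or 2 and 0 adjusted over the list alone (median 0.08, camera adjusted p = 0.182), with 0 lower by DESeq2 and limma-voom and 1 lower at an unadjusted p under 0.05. The ribonucleotide reductase subunit RRM2, in one of the chromosome segments, rose (0.60 ± 0.0785) and E2F8 (0.86 ± 0.153), while MCM6 (0.28 ± 0.077) and UNG (0.35 ± 0.104) each lost the call in 7 of 14 alternative fits. Leaving out control library 2 or any one STAT3 shRNA library gave 2 higher, and leaving out control library 3 gave 1 lower. Of 50 G2/M and mitosis genes, 4 rose and 3 fell, the same counts adjusted over the list alone (median 0.14, camera adjusted p = 0.101). The kinesin genes KIF20B (-1.39 ± 0.192) and CENPE (-2.08 ± 0.409, lost in 4 of 14 alternative fits) fell, as did HJURP (-0.53 ± 0.0854) of the chromosome segments, and NUSAP1 rose (0.88 ± 0.135). Without control library 1 the higher count was 13, without control library 2 or STAT3 shRNA library 1 it was 2, and without STAT3 shRNA library 3 it was 1. Upper-quartile scaling gave 6 higher in each of these lists, and library totals gave 7 G1/S and 8 G2/M genes.

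Of 26 p53 targets, 4 rose and 1 fell, the same counts adjusted over the list alone (median 0.13, camera adjusted p = 0.439). BTG2 rose as given above, ZMAT3 fell (-0.66 ± 0.125), and PPM1D (0.42 ± 0.096) and SESN2 (0.63 ± 0.144) rose but lost the call in 3 of 14 alternative fits each. The higher count was 1 without control library 2 or STAT3 shRNA library 1 and 2 without STAT3 shRNA library 2 or 3, and the lower count was 2 without control library 3. Of 34 BCL2 family and caspase genes, 5 rose and 5 fell, or 6 and 6 adjusted over the list alone (median 0.10, camera adjusted p = 0.907, with camera pointing up and fry down). The initiator caspase CASP9, in one of the chromosome segments, fell from 49.4 ± 3.06 to 10.4 ± 1.86 CPM. The BCL2 relative BOK fell (-1.49 ± 0.147) and DIABLO, an inhibitor of apoptosis inhibitors, (-0.79 ± 0.109), and the pro-apoptotic BCL2L11 rose (1.06 ± 0.146).

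Of 24 epithelial adhesion and junction genes, 8 rose and 3 fell, or 9 and 4 adjusted over the list alone (median 0.15, camera adjusted p = 0.225). The tight junction gene CLDN1 rose from 31.3 ± 1.86 to 118 ± 11 CPM, keratin KRT8 (0.67 ± 0.096) and cingulin (CGN) (1.07 ± 0.155), beside EPCAM. Of 37 mesenchymal, adhesion and matrix genes, 5 rose and 10 fell, or 8 and 12 adjusted over the list alone (median -0.12, camera adjusted p = 0.225). The repressor ZEB2 fell from 6.53 ± 1.12 to 1.34 ± 0.279 CPM, beside FN1, COL1A1 and LOX, and library totals gave 9 higher. Of 19 TGF-beta and BMP targets, 4 rose and 7 fell, or 4 and 8 adjusted over the list alone (median -0.38, camera adjusted p = 0.0998). The BMP antagonist NOG fell from 11.6 ± 2.1 to 2.5 ± 0.55 CPM and the basement membrane collagen COL4A1 (-0.82 ± 0.0996). The count of 4 higher targets was 1 without control library 2 or STAT3 shRNA library 3 and 2 without STAT3 shRNA library 1 or 2. Among 11 beta-catenin targets, 4 rose and 2 fell, or 4 and 3 adjusted over the list alone (median 0.16, camera adjusted p = 0.554). RNF43 rose from 0.129 ± 0.0659 to 3.74 ± 0.977 CPM and BMP4 (1.203 ± 0.133), while ZNRF3 fell (-0.87 ± 0.106); RNF43 and ZNRF3 are related ubiquitin ligases that remove Wnt receptors.

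Ribosomal protein genes were called lower as a list by small amounts, with a median of -0.36 over 75 genes (camera adjusted p = 2.53e-08). The camera adjusted p was 0.534 with an estimated correlation, for which the estimate was 0.67, and ranged from 1.04e-12 to 1.81e-05 over its 9 other alternatives, while fry gave 0.111 and did not call the list. The median was -0.20 without control library 3. Over all genes tested 11 fell and 0 rose, and edgeR with the FDR adjusted over the list alone gave 0 in either direction; at an unadjusted p under 0.05, 44 were lower and 0 higher, DESeq2 gave 25 lower and 0 higher, and limma-voom 10 and 0. With upper-quartile scaling or library totals, 5 were lower. RPS15 (-0.46 ± 0.11), RPL10 (-0.56 ± 0.143), RPL19 (-0.44 ± 0.112) and RPL37A (-1.08 ± 0.241) were lower, with calls lost in 2, 3, 4 and 5 of 14 alternative fits, RPL37A lies in a chromosome segment, and these genes have many processed copies. The 11 lower genes became 52 without control library 1, 1 without control library 2, 6 without control library 3, and 0, 4 and 1 without STAT3 shRNA libraries 1, 2 and 3. The mean log2 CPM of the list was 9.42, 9.68 and 9.95 in the control libraries and 9.26, 9.46 and 9.30 in the STAT3 shRNA libraries, so the groups overlapped.

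Nuclear-encoded respiratory chain genes had a median of -0.30 over 60 genes (camera adjusted p = 1.03e-05), with 6 lower and 0 higher, the same counts adjusted over the list alone. The camera adjusted p was 0.553 with an estimated correlation and ranged from 2.98e-09 to 0.00420 over its 9 other alternatives, while fry gave 0.111 and did not call the list. The median was -0.17 without control library 3. At an unadjusted p under 0.05, 21 were lower and 1 higher, DESeq2 gave 9 lower and 0 higher and limma-voom 7 and 0, while library totals gave 1 higher. NDUFA10 (-0.98 ± 0.0861), SDHB (-0.76 ± 0.0872) and NDUFS1 (-0.67 ± 0.0891) lie in the chromosome segments and NDUFB4 (-0.52 ± 0.0955) does not. Outside the segments 2 members were lower, and without control library 1, 31 were, while 1 was higher without control library 3. The 13 protein genes of the mitochondrial genome gave 0 calls by edgeR over all genes and adjusted over the list alone, 0 at an unadjusted p under 0.05, and 0 by DESeq2 and limma-voom (median 0.02, camera pointing down with adjusted p = 0.723), with MT-CO1 at 9244 ± 1872 and 9386 ± 2283 CPM and MT-CO3 at 4781 ± 765 and 4423 ± 793 CPM. Leaving out control library 1 gave 1 lower.

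Of 39 autophagy and lysosome genes, 2 rose and 9 fell, or 3 and 9 adjusted over the list alone (median -0.09, or 0.01 with library totals, camera adjusted p = 0.0998). ATG9A (-0.87 ± 0.0856) and ATG16L1 (-1.004 ± 0.0999), both needed to form autophagosomes, fell and lie in one of the chromosome segments. The lysosomal galactosidase GLA fell (-0.60 ± 0.0836) and the protease CTSB rose (0.67 ± 0.1004). The higher count was 4 without control library 1. The 9 tested histone genes gave 0 calls by edgeR over all genes and adjusted over the list alone, by DESeq2 and by limma-voom, with 1 higher and 1 lower at an unadjusted p under 0.05 (median -0.15, camera adjusted p = 0.927). HIST1H1C lay at 30.3 ± 1.77 and 35.6 ± 1.95 CPM and HIST1H2BK at 26.7 ± 4.3 and 29.9 ± 0.978 CPM. Without control library 3, 1 histone gene was lower. Neither of the 2 tested metallothioneins was called over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom (median 0.04): MT2A lay at 130.2 ± 12.9 and 134 ± 5.63 CPM and MT1X at 8.68 ± 1.11 and 8.87 ± 0.826 CPM.

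Part of the change was arranged along chromosomes. The search used windows of a gene with its 40 neighbours, over 13178 genes at 1 CPM or more. In 3 segments the window median log2 fold change, relative to all genes, lay beyond 0.379 in size. That was the largest value in 100 shuffles of gene order. The segment on chromosome 1 held 46 genes with a median of -0.55, 84.8% of them below the median of all genes. A segment of 48 genes on chromosome 2 had a median of 0.43, with 89.6% above. The longest, also on chromosome 2, held 307 genes with a median of -0.55, with 89.9% below and 188 called lower. In the STAT3 shRNA libraries the 3 segments lay at -0.59, -0.43 and -0.59, at 0.44, 0.39 and 0.45, and at -0.53, -0.59 and -0.52 in libraries 1, 2 and 3, while each control library lay within -0.12 to 0.10. Together they held 401 genes, or 3.04% of those placed, and 243 called genes, of which 214 were lower and make up 17.6% of all lower calls. Of the genes named above, CASP9 and SDHB lie in the segment on chromosome 1, RRM2 and PDIA6 in the higher one on chromosome 2, and ALPI, FN1, NR4A2, HJURP, PDK1, IRS1, HSPD1, HSPE1, NDUFA10, NDUFS1, RPL37A, ATG9A and ATG16L1 in the long one. Leaving the segment genes out, as chosen after the data were seen, left 2384 called genes, 1379 higher and 1005 lower, 867 of them by at least 2-fold. These counts are those of the same fit and adjustment with the segment genes removed, not of a new fit. Camera run again without the segment genes called 5 lists.

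**Figure D4:**
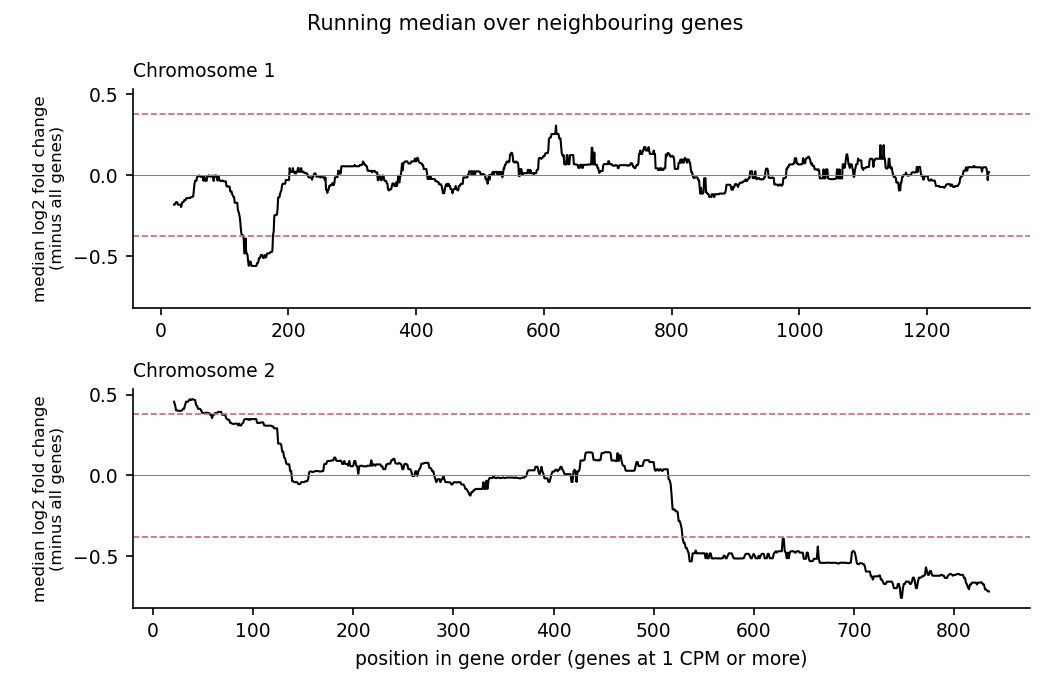
The line is the median log2 fold change (STAT3 shRNA over control shRNA, minus the median of all genes) in windows along chromosomes 1 and 2. Each window is a gene with its 40 neighbours, and the x axis is the position in gene order. The dashed lines mark 0.379 on either side, the largest value in 100 shuffles of gene order. The line leaves that band in 3 segments, 1 on chromosome 1 and 2 on chromosome 2.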

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

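Leaving out the segment genes was chosen after the data were seen; the other alternatives were fixed before. The fall of STAT3 kept its direction and call in all 14 alternative fits, with a log2 fold change between -2.84 and -2.72. Of the 142 called named genes, 122 kept their call and direction in each of the 14 fits that tested them, 0 reversed, and 20 lost the call in at least 1 fit (UNG, STIP1, CPT2, MCM6, CENPE, HSPE1, RPL37A, PPM1D, SESN2, HADHB, PDIA6, ERN1, AHSA1, RPL10, RPL19, RPS15, ACTA2, OSMR, PPP1R3C and CD68). A gene that a fit did not test, such as FAP under the filter at 1 CPM in 3 libraries, was not counted as a loss. The count of called genes lay between 2278 and 2897 over the scalings, filters, tests and the block, against 2627. It was 1354 at an FDR of 0.01, a stricter threshold. With 1 library left out, it ranged from 1462 without STAT3 shRNA library 1 to 4098 without control library 1. It was 1527 without control library 2 and 1475 without STAT3 shRNA library 3. The cause was not tested. Each of these fits kept the same number of libraries, yet the count moved both ways, so that number alone does not account for it. Among pairs within groups, control libraries 1 and 3 differed most, at a chi-square of 43.0 per degree of freedom. Without control library 1, 2503 of the 2627 genes were called again. DESeq2 called 2818, sharing 2446, and limma-voom 2603, sharing 2541. The count of changes of at least 2-fold lay between 763 and 1109 without 1 library, and a test against a 1.5-fold change gave 715, against 924. Of 35 lists, 6 were called; an estimated correlation gave 0, with 1 at an unadjusted p under 0.05, and the fry test, which asks another question, gave 22, while leaving out a library gave 4 to 6. Library numbers did not pair the samples: deviations of same-numbered libraries from their group means correlated at 0.28, 0.19 and -0.23, and not every library correlated best with its own number. With the library number as a block, 2278 genes, 854 with at least a 2-fold change, and 4 lists were called (cholesterol synthesis, glycolysis and hypoxia, respiratory chain and ribosomal proteins), while the immediate early and heat shock lists had a camera adjusted p of 0.0740 each. Among genes that were not called, the sign of the log2 fold change turned without 1 library for MT-CO1 (-0.12 to 0.21, against 0.022), MT-CO3 (-0.22 to 0.035, against -0.11), MT2A (-0.016 to 0.13, against 0.043) and MT1X (-0.072 to 0.12, against 0.03). Depth limits what can be seen: a gene under 0.113 to 0.175 CPM cannot be told from 0. The simulation called 28.4% of 1.5-fold changes, but it changed far fewer genes than were called here. Which share of 1.5-fold changes was missed in these data is therefore not known. The 6 libraries give 10 splits, too few for a share under 0.05. The real split gave 2627 genes and the highest other 35, so 1 of the 10 gave as many; for changes of at least 2-fold the real split gave 924 and the highest other 23, again 1 of 10; for lists the real split gave 6 and the highest other 7, so 2 of 10 gave as many.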

Other observations

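The tests of chromosome copy number, of differences between single libraries, of genes matched for length and GC and of the hepatocyte transcripts were chosen after the result was seen. Some genes outside the naming rule, chosen after their values were seen, add to the account of what these cells express. The imprinted RNA H19 was among the 10 most abundant genes and fell from 8595 ± 3046 to 3067 ± 487 CPM (-1.49 ± 0.251). The placental alkaline phosphatase ALPP, also among these 10, lay at 4898 ± 418 and 3637 ± 171 CPM and its germ cell relative ALPG at 31.4 ± 2.52 and 8.92 ± 0.608 CPM, next to the far larger fall of ALPI, and all 3 lie in the long segment of chromosome 2. CPS1, the first enzyme of the urea cycle, lay at 4642 ± 748 and 3044 ± 171 CPM in the same segment, and keratin KRT7 at 1061 ± 122 and 743 ± 48.6 CPM. AKR1C3 rose with AKR1C2 (0.73 ± 0.0853) while AKR1C1 fell. VIT, a matrix protein gene, and DCLK3, a kinase gene, had no counts in the 3 STAT3 shRNA libraries, at least 37.0-fold and 12.7-fold lower, and JHY had none in the 3 control libraries, at least 11.4-fold higher, each against 3 counts per library.

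Neighbouring genes on chromosomes 1 and 2 changed together, to a median of -0.756 in the window farthest from 0 against at most 0.379 in 100 shuffles of gene order. Separate responses of single genes to the STAT3 shRNA are argued against as the source of the shared shift, where it was checked. Segments found from every other gene predicted the genes in between, 93.5% of 77 lying on the side of the segment with a median shift of 0.59. The segments described above held 401 genes, so the check covered only a part of them. It does not bear on single changes far beyond the shared shift, such as those of ALPI (-7.15 ± 0.219) and FN1 (-3.24 ± 0.309). Different copy numbers of these segments in the lines stay open as a candidate explanation, since the window median is the pattern itself and does not test them. A regional effect of the shRNA stays open as well and was not tested. The calls that follow their segment, 25 and 188 lower and 22 higher, could belong to the lines or to the knockdown, while 8 calls in the segments run against the shared shift.

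Many hepatocyte transcripts were near 0 in libraries labelled HepG2, though not all: HPD lay at 184 ± 25.9 CPM and CPS1 at 4642 ± 748 CPM in the control libraries. Low depth is argued against, since a count of 0 allowed at most 0.175 CPM in any library. For the 8 hepatocyte genes chosen after their values were seen, so is an effect of the STAT3 shRNA, since they summed to at most 0.264 CPM in a control library. Cells other than hepatocyte-like HepG2 and a loss of hepatocyte transcripts within the line both stay open, as the 42.3% of markers with a row that reached 1 CPM in any library restates the pattern. The list of genes of other laboratory lines that HepG2 should lack had 8 members with a row, of which 3 reached 1 CPM in any library. Among them KRT17 lay at 685 ± 91 CPM in the control libraries. These values do not identify the cells. Several hepatocyte genes, such as AFP, TTR and APOB, were not analysed here.

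Ribosomal protein and respiratory chain genes were called lower by camera with its preset correlation, but not with an estimated correlation (camera adjusted p = 0.534 and 0.553) or by fry (0.111 for both). Length and GC content of the longest annotated transcript are argued against as the whole cause. Genes outside the lists matched for both had a median log2 fold change of -0.02, or 5.96% of that of the lists (95% bootstrap interval -2.19 to 12.4). Lengths of the transcripts expressed in these cells were not measured and can be shorter, so a bias tied to those lengths stays open. A fit on length and GC left 102%, but it held only 0.521% of the variance over all genes and so decides nothing. Differences between single libraries within a group may account for the calls: the lowest control library lay -0.102 from the highest STAT3 shRNA library in mean log2 CPM of the respiratory chain list, and the groups overlapped in both lists. The STAT3 shRNA stays among the open explanations.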
